A study of Homo sapiens with 16 samples.

How the data were processed

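The series holds 16 PRO-seq samples of Kasumi-1 cells: 2 of the parental line and 14 of a line whose SMARCA5 alleles carry an FKBP12F36V tag, untreated or treated with 500 nM dTAG-47 for 2, 6 or 24 h. Nuclear run-on RNA was isolated with Trizol, biotinylated RNA was enriched on streptavidin beads, hydrolysed and ligated to adaptors, per the labels. The submitters' processing notes name Trimmomatic 0.32, Bowtie2 2.2.2, SAMtools, HOMER, DESeq and DESeq2 and the hg19 assembly. The counting tool, the windows that define promoter-proximal regions and gene bodies, the strand counted and the limit of any prior filter are not given in the sources used here. Reads of overlapping or divergent genes therefore cannot be told apart.

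The 6 deposited tables give 3 comparisons (2, 6 and 24 h against 0 h) for each of 2 regions, over 10304 RefSeq transcripts, of which 18 share a gene symbol with another. They contain raw read counts of the 14 tagged libraries, which the authors counted per transcript, and these counts were identical in the 3 tables of a region. The deposited mean signal per transcript is the mean of counts divided by library size factors. It was recomputed within a relative deviation of 4.9e-15 from median-of-ratios factors of the gene-body counts, applied to both regions. The tables also give the authors' DESeq2 log2 fold changes with standard errors, the authors' Wald statistic as a score, and the authors' p-values with adjusted p-values. The authors' tables call 4125, 2930 and 2304 genes in gene bodies at 2, 6 and 24 h, and 78, 93 and 38 near promoters, at an adjusted p under 0.05. Near promoters 15, 5 and 9 of these rose and 63, 88 and 29 fell. DESeq2 with a run term, run here as an alternative, gave the same gene-body counts in each direction and the same medians. The model below has no such term. Near promoters it gave 704, 358 and 242. The 84 deposited normalized columns, 14 in each table, were not used. The tables hold no column for the parental line, so untreated tagged cells were not compared with it. The column names give the time, a letter and a run number but not the replicate number of the sample labels, so libraries are named by letter and run. Transcript coordinates are given as listed, with the first base and strand not stated.

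Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, separately for gene bodies and promoter-proximal regions. Transcripts passed edgeR's default expression filter (10304 in gene bodies, 9980 near promoters), libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per time was fitted to all 14 libraries. Each time was tested against 0 h, and 24 h and 6 h against 2 h, with Benjamini-Hochberg adjustment over transcripts and a threshold of 0.05. Levels are CPM, read counts scaled by library size and TMM factor, and log2 fold changes carry the model's standard error. Promoter-proximal minus gene-body change was computed from per-library log2 differences (prior count 2) and tested with limma. The 28 gene lists were fixed before the data were examined, and 23 had at least 5 measured members. They were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over 138 tests of 23 lists, 3 times and 2 regions, and again with the correlation estimated from the data. Of 18 list calls against 0 h, 0 held with the estimated correlation (camera; 21 held or were new with a run term), and that p is given beside each call. The promoter-proximal share of reads was compared by two-sided exact permutation tests.

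The comparisons, the thresholds, the rule for named genes and 1 set of alternatives were also fixed before the data were examined. The rule took, for each time and region, the 8 largest rises and 8 largest falls among called genes with a mean normalized count of at least 100. It added up to 5 genes per direction called at all 3 times, SMARCA5, and up to 4 members of each list with the smallest adjusted p, and any member needed to describe a list. A few genes that the rule gives are not reported here. Genes outside it are named as chosen after their values were seen. Where a symbol had 2 transcripts, as for RUNX1, the one with the higher mean is given. Alternatives fixed in advance were a rank-based camera test, a threshold of 0.01, a minimum fold of 1.5, a minimum mean count of 100, 1 transcript per symbol, DESeq2 1.42.0, its size factors, no filter, only the groups compared, a term for the first against the later deposited samples, and leaving out each library. A term for the run, run 2 alone, omission of both untreated libraries of run 1, gene-body size factors for promoter-proximal counts, and DESeq2 with a run term were added after seeing the data.

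The tests were tested on simulated counts with known changes, drawn around the mean of each gene over all 14 libraries. Differences between runs were not simulated, and changed genes were drawn only above a minimum mean. The rates below may therefore not hold for the real libraries. In gene bodies 2-fold changes were recovered for 95.5, 89.6 and 80.6% of genes at 2, 6 and 24 h and 1.5-fold changes for 59.7, 56.7 and 37.3%. Near promoters 2-fold changes were recovered for 32.8, 19.4 and 16.4% and 4-fold changes for 93.9, 98.5 and 80.3%, and 4-fold changes of the promoter-proximal minus gene-body difference for 89.4, 95.5 and 71.2% (2-fold, 5.97, 13.4 and 2.99%). For that difference 8.57, 3.90 and 15.5% of the simulated calls were false. Gene-body totals of 11182894 to 34209362 reads and promoter-proximal totals of 1667950 to 7171601 per library were not varied to test the effect of depth.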

Results

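PRO-seq, which maps RNA polymerases engaged on the genome through run-on labelling of nascent RNA, was performed in Kasumi-1 cells, an acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion. Both alleles of SMARCA5, the ATPase of the ISWI chromatin remodellers that slide and space nucleosomes, carried an FKBP12F36V tag, through which dTAG-47 directs the protein to degradation. The tagged cells were sampled untreated (0 h, n = 5) and after 2 h (n = 3), 6 h (n = 4) and 24 h (n = 2) with 500 nM dTAG-47. Reads were counted in the gene body and in the promoter-proximal region of 10304 RefSeq transcripts listed on hg19. Gene-body totals ranged from 11182894 to 34209362 reads per library and promoter-proximal totals from 1667950 to 7171601. The libraries, named A or B within each time, fell into 3 runs, numbered here after a code in the column names whose meaning the sources do not give. Run 1 held untreated libraries of 30537369 and 30066879 gene-body reads and a 2 h library of 34209362. Run 2 held untreated libraries of 16138846 and 11199143 reads and 2 h libraries of 13142254 and 14133770. Its 6 h libraries held 11182894 and 13410723 and its 24 h libraries 12251127 and 13146389. Run 3 held an untreated library of 17526557 and 6 h libraries of 23893255 and 26130746. The 24 h time point was thus measured in run 2 alone. Gene-body counts of libraries of the same time correlated across genes with Spearman coefficients of 0.992 to 0.998 within a run and 0.967 to 0.993 between runs. Promoter-proximal counts gave 0.938 to 0.986 within a run and 0.862 to 0.971 between runs. The untreated libraries of run 1 stood apart from all others on the first principal component of gene-body counts, which held 46.8% of the variance (scores -46.6 and -37.1, against -10.1 to 28.4). On that of promoter-proximal counts (34.7%) run 3 stood apart, with its 6 h libraries at 70.1 and 42.95 and its untreated library at 28.4, against -28.9 to 2.11. P-values of single genes and of the promoter-proximal share rest on the spread between these libraries. The series calls the libraries biological replicates without saying whether each came from a separate culture. Camera p-values at the preset correlation compare the genes of a list with all other genes, so they do not measure that spread.

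Transcription of the target gene itself, SMARCA5 (NM_003601, chromosome 4, 144434616 to 144478642), showed no change that passed the test at any time. The tag acts on the protein, so the level of the transcript does not report how much SMARCA5 was lost. Its gene body held 113 ± 20.6 CPM in untreated cells (SD, n = 5), 94.2 ± 9.04 at 2 h (n = 3), 96.4 ± 9.31 at 6 h (n = 4) and 96.8 ± 11.4 at 24 h (n = 2). The highest values were those of both untreated libraries of run 1 (147 and 118), and the other untreated libraries held 98.3 to 102. Log2 fold changes against 0 h were -0.27 ± 0.13 (SE; adjusted p = 0.178), -0.24 ± 0.12 (0.148) and -0.23 ± 0.15 (0.350) in edgeR with Benjamini-Hochberg adjustment. In run 2 alone the 6 h change was 0.039 (adjusted p = 0.719). Near the SMARCA5 promoter the runs differed at 6 h. Libraries of run 2 held 52.5 and 53.5 CPM, against 34.8 and 36.0 untreated, and those of run 3 held 33.8 and 27.5, against 28.1. Among the 12 measured ISWI subunit genes, RSF1, a histone-binding partner of SMARCA5, fell at 2 h (-0.24 ± 0.074) and 6 h (-0.24 ± 0.068). BAZ1A, the large subunit of the ACF and CHRAC remodellers, fell at 6 h (-0.32 ± 0.10). BAZ1A was not called with a run term (adjusted p = 0.0878). The list's median at 2 h was -0.37 in run 1, with 10 of 12 lower, and 0.0027 in run 2, with 6 lower. At 6 h it was -0.040 in run 3 and 0.048 in run 2, with 9 and 4 lower. Per library the list stood highest in the untreated libraries of run 1 (median deviations of 0.31 and 0.25, against -0.25 to 0.021). Adjusted over the list alone, 0 fell at 2 h (2 at an unadjusted p under 0.05; 1 in DESeq2 over all genes) and 2 at 6 h. At 24 h edgeR called 0 of the 12 (1 at an unadjusted p under 0.05; 0 in DESeq2).

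The comparison of 2 h with untreated cells asked which genes gained or lost engaged polymerase, relative to other genes, soon after SMARCA5 degradation was triggered. Libraries were scaled on these counts themselves, so a change common to most genes is removed, here and at later times. The balance of rises and falls therefore does not show whether total transcription changed. PTPRF, a receptor tyrosine phosphatase (NM_002840, chromosome 1, 43996547 to 44089343), showed the largest fall among genes with a mean of at least 100 normalized counts. It went from 45.7 ± 6.84 CPM in untreated cells (SD, n = 5) to 7.25 ± 1.68 at 2 h (n = 3). The log2 fold change was -2.67 ± 0.27 (SE; adjusted p = 1.4e-04). Other large falls were those of TBCEL (-1.75), ZNF711 (-1.61) and CCDC71L (-1.53) and of E2F5, a repressor of the E2F family (-1.65). TERT, the catalytic subunit of telomerase, fell (-1.05 ± 0.21; adjusted p = 0.00741), and so did PGM1, a phosphoglucomutase (-1.06 ± 0.10, 1.4e-04). The largest rises were those of enzymes that make mevalonate and cholesterol, MVD (2.34 ± 0.45, adjusted p = 0.00577), MVK (1.95 ± 0.41), HMGCS1 (1.88 ± 0.45) and MSMO1 (1.74 ± 0.37). SGCB, which encodes beta-sarcoglycan, rose by 1.61 ± 0.26, and ABCC5, an efflux transporter, by 0.78 ± 0.071. In all, 618 genes rose and 747 fell among 10304 (edgeR quasi-likelihood test, Benjamini-Hochberg), with a median absolute log2 change of 0.49, and 108 of the 1365 exceeded 2-fold. Over all genes, called or not, the changes within run 1 and within run 2 correlated with a Spearman coefficient of 0.461. A fit with a term for the run called 3979 genes, and 1365 of these were called in the same direction without it. The count moved to 322 without 2 h B of run 1 and 550 without 2 h B of run 2. It was 732 without 2 h A of run 2 and 2248 without 0 h A of run 3. Without 2 h library B of run 1, the calls of MVD (adjusted p = 0.0547), MVK (0.0735), HMGCS1 (0.172), MSMO1 (0.0813) and TERT (0.0546) were lost.

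Cholesterol synthesis genes moved furthest among the gene lists at 2 h: 19 of 24 measured members rose and 5 were not called, with a median log2 change of 1.13 (adjusted p = 8.1e-14, and adjusted p = 0.886 with an estimated correlation). Adjusted over the list alone, 20 rose. NSDHL, a sterol dehydrogenase, rose by 1.10 ± 0.20 (adjusted p = 0.00457). INSIG1, which retains the sterol-regulated SREBP complex in the endoplasmic reticulum, rose by 1.47 ± 0.32. INSIG1 lost its call without 2 h library B of run 1 (adjusted p = 0.0949), while NSDHL kept its call in every fit without 1 library. The median of the list was 1.75 in run 1, where 24 of 24 members were higher, and 0.65 in run 2, where 22 were. Of 27 heat shock and unfolded protein response genes, 4 rose and 1 fell (median 0.33; adjusted p = 0.00228, and adjusted p = 0.693 with an estimated correlation; 6 rose and 1 fell adjusted over the list alone). They included DNAJB1, an HSP70 co-chaperone (0.80 ± 0.12), and HERPUD1, a gene of the endoplasmic reticulum stress response (0.70 ± 0.14; adjusted p = 0.0589 without 2 h library B of run 1). The list's median was 0.76 in run 1 and 0.15 in run 2, and its call was lost in run 2 alone.

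Genes of glycolysis and the hypoxia response were lower at 2 h, with 8 of 23 falling and 1 rising (median -0.26; adjusted p = 0.00501, and adjusted p = 0.886 with an estimated correlation; 9 fell and 2 rose adjusted over the list alone). PDK1, a kinase that inhibits pyruvate dehydrogenase (-0.82 ± 0.11), SLC2A1, a glucose transporter (-0.75 ± 0.11), BNIP3L, a mitophagy receptor (-0.64 ± 0.097), and PFKP, a phosphofructokinase (-0.56 ± 0.084), fell. The list's median was 0.025 in run 1 and -0.37 in run 2, and a rank-based test lost its call. Among 21 transcripts of haematopoietic and leukaemia transcription factors, 8 fell (median -0.043; adjusted p = 0.0403, and adjusted p = 0.886 with an estimated correlation; 8 fell and 2 rose adjusted over the list alone). The ETS factors FLI1 (-0.48 ± 0.076) and ETV6 (-0.45 ± 0.070), the zinc-finger repressor ZEB2 (-0.93 ± 0.18) and RUNX1 (-0.28 ± 0.061) fell. The list's median was -0.024 in run 1, with 10 higher and 11 lower, and -0.31 in run 2. RUNX1 was no longer called without 2 h library B of run 1 (adjusted p = 0.0663). The list's call was lost without any of 6 libraries, namely 0 h A and B of run 2 (0.151 and 0.145), 2 h A of run 2 (0.148, with a median of 0.010, of the opposite sign), 6 h A and B of run 2 (0.0509 and 0.0561) and 6 h A of run 3 (0.0598). It was also lost in a rank-based test (0.198). Of 25 SWI/SNF, CHD and INO80 remodellers, 2 fell (median -0.12; adjusted p = 0.0258, and adjusted p = 0.886 with an estimated correlation; 5 fell adjusted over the list alone), namely CHD7 (-0.69 ± 0.14) and SMARCA2 (-0.29 ± 0.085). That call was lost without 0 h library B of run 1 (0.0698) or both 0 h libraries of run 1 (0.227) and in run 2 alone (0.165). Of 39 replication genes, 4 rose, among them POLA2, a DNA polymerase alpha subunit (median 0.11; adjusted p = 0.0169, and adjusted p = 0.922 with an estimated correlation; 4 adjusted over the list alone). This call was lost without 0 h A of run 3 (0.176), 0 h A or B of run 2 (0.0854, 0.0596) or 2 h A of run 2 (0.0891), and with a run term (0.0696). The list's median was -0.046 in run 1, with 14 of 39 higher, and 0.28 in run 2, with 37 higher.

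At 6 h the question was whether the early changes spread or reverted. PTPRF remained the gene with the largest fall, at -2.68 ± 0.24 (SE; n = 4 against 5; adjusted p = 1.1e-05). TERT (-1.72 ± 0.20, 8.4e-05), CCDC71L (-2.23), TBCEL (-2.02) and GGT7, of the gamma-glutamyltransferase family (-2.03), also fell. Large rises were those of CD22, a sialic-acid-binding lectin (2.15 ± 0.30, adjusted p = 3.3e-04), LOC728743 (1.90) and TBC1D2, a GTPase-activating protein for Rab proteins (1.71 ± 0.13). TMEM8B (1.61), NOL3, an inhibitor of apoptosis (1.60), SGCB (1.57) and LOC100129722 (1.53) rose as well. In all, 1533 genes rose and 1477 fell among 10304, with a median absolute log2 change of 0.46, and 194 exceeded 2-fold. Over all genes the changes within run 2 and within run 3 correlated with a coefficient of 0.552. Of the 3010 called genes, 2237 were called in the same direction with a run term, which called 2762. Without 6 h library B of run 3 the count fell to 1854. The fall of ZNF35 (-1.84 ± 0.52) was -0.44 within run 3 and -0.50 within run 2 and was not called with a run term (adjusted p = 0.124). That of EGR1, an immediate early transcription factor (-2.17 ± 0.53), was 0.031 within run 3 and -3.18 within run 2.

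Ribosome biogenesis genes were lower at 6 h: 18 of 29 measured members fell and 11 were not called, with a median log2 change of -0.34 (adjusted p = 3.6e-07, and adjusted p = 0.349 with an estimated correlation). Adjusted over the list alone, 19 fell. The nucleolar factors NOLC1 (-0.81 ± 0.13), WDR43 (-0.61 ± 0.093) and HEATR1 (-0.45 ± 0.072) and POLR1B, a subunit of RNA polymerase I (-0.53 ± 0.076), were among them. The median was -0.25 within run 3 and -0.35 within run 2. Of 51 genes for cytosolic ribosomal proteins, 8 fell (median -0.15; adjusted p = 0.0258, and adjusted p = 0.886 with an estimated correlation; 3 fell adjusted over the list alone). Among the 8 were RPL34 (-0.54 ± 0.11) and RPL22 (-0.35 ± 0.074). This call was lost without 0 h library B of run 2 (0.059) or 6 h library B of run 2 (0.0564). Of the cholesterol synthesis genes, 9 of 24 rose (median 0.62; adjusted p = 0.00652, and adjusted p = 0.922 with an estimated correlation; 13 adjusted over the list alone), but the runs differed. The median was 0.83 within run 3 and -0.042 within run 2. MVD rose by 1.70 ± 0.42, with 1.98 in run 3 and 0.22 in run 2. The list's call was lost without 6 h library A (0.0598) or B (0.0562) of run 3. Glycolysis and hypoxia genes remained lower, with 7 of 23 falling and 1 rising (median -0.15; adjusted p = 0.0403, and adjusted p = 0.922 with an estimated correlation; 9 fell and 1 rose adjusted over the list alone). Among them were PDK1 (-0.92 ± 0.098), SLC2A1 (-0.65 ± 0.10) and ENO1, an enolase (-0.52 ± 0.083). Their median was -0.055 in run 3 and -0.44 in run 2, and a rank-based test lost the list's call. The call was lost without 0 h A of run 3 (0.0607), 0 h A of run 2 (0.143), 0 h B of run 2 (0.149), 2 h A of run 2 (0.0537), 6 h A of run 2 (0.0835), 6 h B of run 2 (0.0869) or 6 h B of run 3 (0.0553). Of 39 replication genes 10 rose at 6 h, and the list did not pass (adjusted p = 0.139), with 36 higher in run 3 (median 0.20) and 34 in run 2 (0.22). With a run term 3 more lists passed at 6 h. They were replication genes (adjusted p = 7.0e-04, and adjusted p = 0.862 with an estimated correlation), haematopoietic factors (0.00175; 0.452) and interferon-stimulated genes (0.0105; 0.360).

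The 24 h comparison (n = 2 against 5) asked which changes lasted and which appeared late. PTPRF (-3.59 ± 0.36, SE), LOC254896 (-3.32 ± 0.29), GGT7 (-3.23 ± 0.52) and TERT (-2.78 ± 0.29; NM_001193376, chromosome 5, 1253287 to 1295162) had the largest falls, with adjusted p-values of 6.7e-05, 3.5e-05, 0.00183 and 9.4e-05. TERT went from 57.4 ± 7.17 CPM (SD, n = 5) to 8.34 ± 0.456 (n = 2). CDK18, a PCTAIRE-family kinase (-2.11), RASL10B (-1.94) and TBCEL (-2.22) also fell. Rises included LOC100505746 (2.13 ± 0.29), DPEP2, a membrane dipeptidase (1.58 ± 0.19, adjusted p = 2.1e-04; NM_022355, chromosome 16, 68021293 to 68033364), LOC728743 (1.57 ± 0.27), and CD33, a sialic-acid-binding receptor of myeloid cells (0.92 ± 0.11, 2.4e-04; NM_001082618, chromosome 19, 51728335 to 51743274). In all, 578 genes rose and 533 fell among 10304, with a median absolute log2 change of 0.60, and 181 exceeded 2-fold. Of the 1111, 1072 were called in the same direction with a run term, which called 2045. All 24 h libraries belonged to run 2, so no second run gives a value. Without 24 h library A the count was 161 and without B it was 200. The genes named so far in this paragraph kept their calls in both of those fits. The rises of CD22 (1.74; adjusted p = 0.0989 without A, 0.0692 without B), ADAM12 (1.69; 0.124, 0.149), NOL3 (1.66; 0.0802, 0.0644), VSIG4 (1.60; 0.23, 0.269) and LOC400604 (1.54; 0.0845, 0.185) and the fall of ALDH1L2 (-2.68; 0.24, 0.224) were lost in each. VSIG4 was also lost without 0 h A of run 1 (0.0733) and ALDH1L2 without 0 h B of run 1 (0.0516).

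Mitosis genes were higher at 24 h: 8 of 33 rose and 25 were not called, with a median log2 change of 0.31 (adjusted p = 9.0e-07, and adjusted p = 0.886 with an estimated correlation). Adjusted over the list alone, 12 rose, and 32 of 33 were higher within run 2. They included the proliferation marker MKI67 (0.60 ± 0.11), the mitotic phosphatase CDC25C (0.52 ± 0.093), the transcription factor FOXM1 (0.66 ± 0.12) and the centromeric histone CENPA (0.82 ± 0.19). Of 16 interferon-stimulated genes, 5 rose (median 0.39; adjusted p = 0.0250, and adjusted p = 0.886 with an estimated correlation; 6 rose adjusted over the list alone). Among them were IFI6 (1.45 ± 0.32), IFI27 (0.99 ± 0.22), the RNA sensor IFIH1 (0.58 ± 0.13) and the ISG15 ligase HERC5 (0.68 ± 0.14). This list's call was lost without 0 h library A (0.102) or B (0.0596) of run 2. Ribosome biogenesis genes stayed lower, with 5 of 29 falling (median -0.23; adjusted p = 8.0e-04, and adjusted p = 0.671 with an estimated correlation; 9 fell adjusted over the list alone). They included WDR43 (-0.50 ± 0.12), WDR12 (-0.41 ± 0.089) and the RNA polymerase I subunit POLR1A (-0.38 ± 0.082). Of 23 glycolysis and hypoxia genes, 7 fell and 1 rose (median -0.21; adjusted p = 0.0470, and adjusted p = 0.922 with an estimated correlation; 7 fell and 2 rose adjusted over the list alone). PDK1 (-0.99 ± 0.13) and PFKP (-0.63 ± 0.098) were among those that fell. A rank-based test lost the call of these glycolysis and hypoxia genes. This list's call was lost without 0 h A of run 3 (0.0570), 0 h A of run 2 (0.147), 0 h B of run 2 (0.157), 2 h A of run 2 (0.0603), 2 h B of run 1 (0.0538), 6 h A of run 2 (0.0509), 6 h B of run 2 (0.0561), 6 h B of run 3 (0.0509) or 24 h B of run 2 (0.0843). For cholesterol synthesis genes, 0 of 24 rose or fell in edgeR (0 at an unadjusted p under 0.05; 0 in DESeq2) and the median was -0.21 (adjusted p = 0.394). Within run 2, 22 of the 24 were lower, with a median of -0.30. Without 24 h library A the calls of MKI67 (adjusted p = 0.0724), CDC25C (0.115), FOXM1 (0.102), CENPA (0.169), IFI6 (0.142), IFI27 (0.0711), IFIH1 (0.0934), HERC5 (0.197), WDR43 (0.124), WDR12 (0.102) and POLR1A (0.0941) were lost. Without library B those of CENPA (0.0917), IFI6 (0.0851), IFI27 (0.189), IFIH1 (0.156), WDR43 (0.176), WDR12 (0.15) and POLR1A (0.146) were lost.

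**Figure D1:**
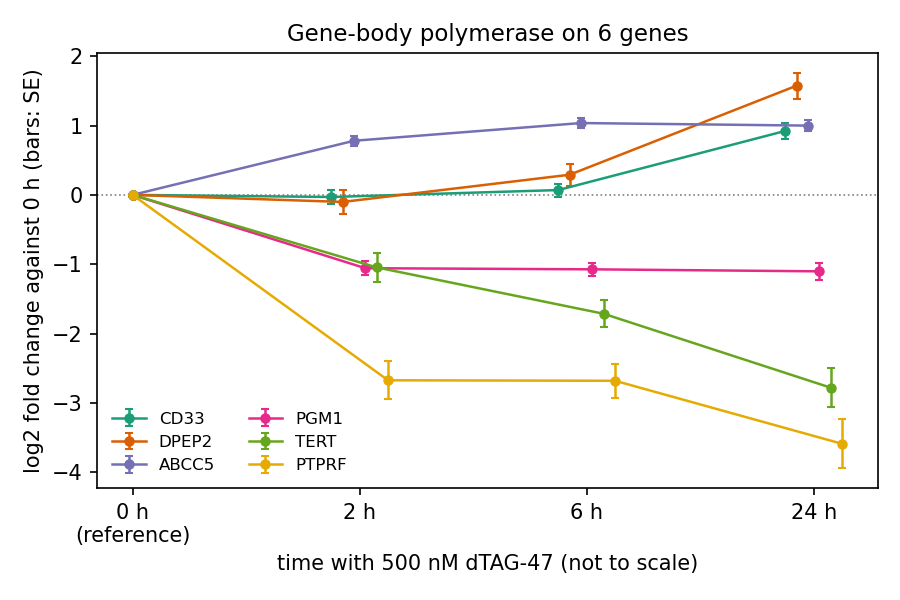
Log2 fold changes of gene-body counts against 0 h (bars, SE; n = 3, 4 and 2 against 5) for 6 genes at 2, 6 and 24 h of dTAG-47. PTPRF and TERT reached -3.59 and -2.78 at 24 h, ABCC5 lay between 0.78 and 1.04 throughout, and CD33 and DPEP2 were higher at 24 h (0.92 and 1.58).

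**Figure D2:**
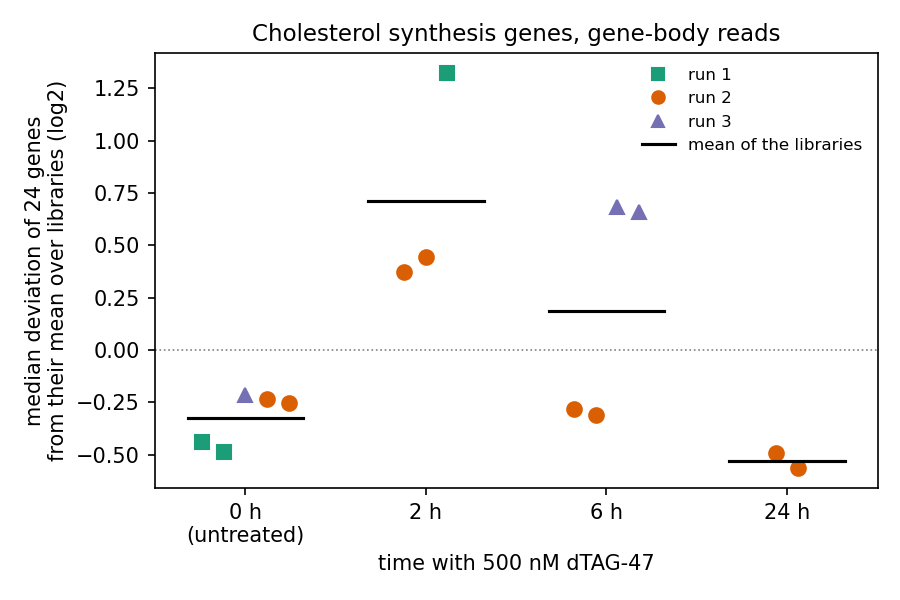
Median log2 deviation of the 24 cholesterol synthesis genes from their mean over libraries, for each library by time and run (lines, mean of the libraries). The 3 libraries at 2 h lay at 0.37 and 0.44 (run 2) and 1.32 (run 1), those at 6 h at -0.28 and -0.31 (run 2) and 0.68 and 0.66 (run 3), and all untreated and 24 h libraries lay below 0.

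Promoter-proximal counts were compared to see where polymerase accumulated or was lost near transcription start sites. TTC8, a subunit of the BBSome (NM_144596, chromosome 14, 89290978 to 89344335), rose by 2.42 ± 0.32 on the log2 scale at 2 h (SE; n = 3 against 5; adjusted p = 0.00489) and 2.25 ± 0.31 at 6 h (n = 4; 0.00344). Also at 2 h, RPGRIP1L, of the ciliary transition zone (2.35 ± 0.36), OBFC2B, which binds single-stranded DNA (1.80 ± 0.30), and TDRKH, a Tudor domain protein (1.69 ± 0.29), rose; RPGRIP1L and TDRKH were chosen after their values were seen. PRPF40B, a splicing factor, rose at all 3 times (2.11 ± 0.35, 2.01 ± 0.33 and 2.52 ± 0.38), and DPH3, a factor in diphthamide synthesis, fell at all 3 (-1.503 ± 0.27, -1.40 ± 0.24 and -1.73 ± 0.33). At 6 h, EZR, which encodes the membrane linker ezrin, fell (-1.81 ± 0.28, adjusted p = 0.00579), as did DIAPH2, a formin (-1.62 ± 0.25), while the SUMO ligase PIAS3 (1.58), OBFC2B (1.37) and LINC00265 (1.36) rose. In all, 5 genes rose and 1 fell at 2 h, 68 rose and 95 fell at 6 h, and 10 rose and 10 fell at 24 h, among 9980 tested. The promoter-proximal region held few reads, with a median of 116 per gene and library. Over all genes the changes within 2 runs correlated with coefficients of 0.261 at 2 h and 0.312 at 6 h, and a run term gave 460 genes (243 rose, 217 fell), 224 (80, 144) and 141 (63, 78). With the gene-body size factors in place of scaling on promoter-proximal counts, the median of all genes shifted to -0.18, -0.21 and -0.081, and 1, 29 and 4 genes were called, of which 1, 6 and 3 rose and 0, 23 and 1 fell. The authors' tables, which use that scaling and another model, hold 15 rises and 63 falls at 2 h, 5 and 88 at 6 h, and 9 and 29 at 24 h. Because the strand used for counting is not given, reads of a divergent neighbour cannot be told apart from those of the gene, as at OBFC2B and DPH3.

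Several promoter-proximal calls rested on single libraries. The balance at 6 h turned without 0 h A of run 3 (471 rose, 346 fell), 6 h A of run 2 (120, 93) or 6 h B of run 2 (146, 118). The 2 h count of 6 moved to 0 without 2 h B of run 1, and 1 without 0 h B of run 1, 2 h A of run 2 or 2 h B of run 2. It was 2 without 0 h B of run 2 and 3 without 0 h A of run 1. The count was 50 without 0 h A of run 3. The 6 h count of 163 moved to 33 without 6 h B of run 3 and 68 without 0 h B of run 1. It was 71 without 6 h A of run 3 and 73 without 0 h A of run 2 or 0 h B of run 2. The count was 90 without 0 h A of run 1 and 264 without 6 h B of run 2. There were 817 without 0 h A of run 3. The 24 h count of 20 moved to 0 without 24 h A of run 2 or 24 h B of run 2 and 9 without 0 h A of run 1 or 0 h B of run 1. It was 10 without 0 h B of run 2 and 13 without 0 h A of run 2. The count was 36 without 0 h A of run 3. TTC8, PRPF40B, DPH3, EZR, DIAPH2 and LINC00265 kept their 6 h calls in every fit without 1 library. At 2 h the call of TTC8 was lost without 2 h B of run 1 (0.0635). That of RPGRIP1L was lost without 0 h B of run 1 (0.0543), 2 h A of run 2 (0.0707), 2 h B of run 2 (0.129) or 2 h B of run 1 (0.0635). PRPF40B lost its 2 h call without 0 h B of run 1 (0.0809), 0 h B of run 2 (0.0814), 2 h A of run 2 (0.0707), 2 h B of run 2 (0.166) or 2 h B of run 1 (0.148). DPH3 lost its 2 h call without 0 h A of run 1 (0.0640), 0 h B of run 1 (0.0809), 0 h B of run 2 (0.0814), 2 h A of run 2 (0.380), 2 h B of run 2 (0.236) or 2 h B of run 1 (0.148). OBFC2B and TDRKH lost theirs at 2 h without any 2 h library or any untreated library of run 1 or 2 (adjusted p from 0.0640 to 0.220). At 6 h PIAS3 lost its call without 6 h B of run 3 (0.0570). OBFC2B lost its call at 6 h without 0 h A of run 1 (0.0521), 0 h B of run 1 (0.0636), 0 h A of run 2 (0.0594), 0 h B of run 2 (0.0552) or 6 h B of run 3 (0.104). The falls of ZNF35 (-2.87; 85.4 ± 97.2 CPM at 0 h, SD, n = 5) and SPRY1, a feedback inhibitor of receptor tyrosine kinases (-2.11), at 6 h were not called with a run term (adjusted p = 0.0744 and 0.0525). ZNF35 lost its call without 6 h A of run 3 (0.0647) or 6 h B of run 3 (0.0954), and SPRY1 without 0 h A of run 1 (0.0641), 0 h B of run 1 (0.0612), 6 h A of run 3 (0.0806) or 6 h B of run 3 (0.126). At 24 h RALGAPA1 (-1.87), PACSIN3 (-1.76) and DIAPH2 (-1.64) fell and MGC16275 (1.68) and LINC00265 (1.55) rose. These calls and those of DPH3 and PRPF40B were lost without 24 h A or 24 h B of run 2 (adjusted p from 0.0848 to 0.764). All but those of RALGAPA1 and PRPF40B were also lost without 0 h A or B of run 1 or 0 h B of run 2, and without 0 h A of run 2 except for DPH3 (0.0511 to 0.0634).

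Among the gene lists, cholesterol synthesis genes were higher near promoters at 2 h, with a median log2 change of 0.63 over 24 members (adjusted p = 6.1e-08, and adjusted p = 0.656 with an estimated correlation). Over all genes edgeR called 0 of them (14 at an unadjusted p under 0.05; 1 in DESeq2), and 10 rose adjusted over the list alone. With a run term 9 members rose. Interferon-stimulated genes were higher at 6 h (median 0.35; adjusted p = 0.0258, and adjusted p = 0.693 with an estimated correlation), with 1 of 16 rising and 5 adjusted over the list alone. Zinc finger genes with a ZNF symbol were lower at 6 h (median -0.12; adjusted p = 0.0350, and adjusted p = 0.693 with an estimated correlation), with 13 of 363 falling and 2 rising, and 27 and 7 adjusted over the list alone. Mitosis genes were higher at 24 h (median 0.28; adjusted p = 0.00652, and adjusted p = 0.886 with an estimated correlation), with 0 of 33 called by edgeR (1 at an unadjusted p under 0.05; 0 in DESeq2) and 0 adjusted over the list alone. The interferon list lost its call without 0 h A of run 3 (0.061), 0 h B of run 2 (0.0584), 2 h A of run 2 (0.0553) or 6 h A of run 3 (0.0654). The ZNF list lost it without 0 h A or B of run 1 (0.0583, 0.0688), 0 h A of run 3 (0.0543), 6 h A or B of run 2 (0.0724, 0.0503) or 6 h A of run 3 (0.0901). The mitosis list lost it without 24 h B (0.101). With a run term the ZNF list had an adjusted p of 0.122 and the mitosis list 0.246. In run 2 alone the calls of the cholesterol, interferon, ZNF and mitosis lists were all lost.

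The change near the promoter minus the change in the gene body asked whether polymerase was redistributed along single genes. Each region was scaled on its own counts, so a shift common to most genes is removed and this measure cannot show it. TTC8 gained promoter-proximal relative to gene-body polymerase at 2 h (2.37 ± 0.36 on the log2 scale, SE, n = 3 against 5; adjusted p = 0.0321 in limma) and 6 h (2.19 ± 0.34, 0.0199). PDE4A, a cyclic AMP phosphodiesterase, gained at 6 h (2.35 ± 0.42) and 24 h (3.22 ± 0.53), and RPGRIP1L at 6 h (1.61 ± 0.27). BTBD6 lost at 2 h (-1.90 ± 0.30, 0.0321), and at 24 h the transcription factor gene TFAP2E (-2.40 ± 0.40), DPH3 (-2.003 ± 0.33), RALGAPA1 (-1.60 ± 0.27) and the polyamine oxidase gene PAOX (-2.30 ± 0.40) lost, while ZNF444 gained (1.93 ± 0.34). The rule for named genes does not cover this measure, so the genes named here were chosen after their values were seen. In all, 1 gene gained and 1 lost at 2 h, 11 gained and 20 lost at 6 h, and 2 gained and 4 lost at 24 h. A run term gave 115, 39 and 25 genes. The 2 h count of 2 moved to 0 without any untreated library of run 1 or 2 or any 2 h library. The 6 h count of 31 moved to 0 without 0 h B of run 1 or 6 h B of run 3 and 4 without 6 h A of run 3. It was 8 without 6 h B of run 2 and 9 without 0 h B of run 2. The count was 14 without 0 h A of run 1 and 17 without 6 h A of run 2. There were 18 without 0 h A of run 2 and 142 without 0 h A of run 3. The 24 h count of 6 moved to 0 without 0 h B of run 2, 24 h A of run 2 or 24 h B of run 2, and 11 without 0 h A of run 3. At 6 h TTC8 lost its call without 0 h B of run 1 (0.0652) or 6 h B of run 3 (0.0536). RPGRIP1L lost its call without 0 h B of run 1 (0.0652), 6 h B of run 2 (0.0553) or 6 h B of run 3 (0.0764). PDE4A lost its 6 h call without 0 h A of run 1 (0.0576), 0 h B of run 1 (0.0652), 0 h B of run 2 (0.0513), 6 h A of run 2 (0.0637), 6 h B of run 2 (0.0560) or 6 h B of run 3 (0.0536). At 24 h PAOX also lost its call without 0 h A or B of run 1 (0.0635, 0.0692) and PDE4A without 0 h A of run 1 (0.0525). TFAP2E lost its call without 0 h B of run 1 (0.0692), RALGAPA1 without 0 h A of run 2 (0.0724) and ZNF444 without 0 h A of run 1 (0.0577) or run 2 (0.102).

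With the runs ignored, the total share of promoter-proximal reads did not differ from untreated cells by more than the spread between libraries. That spread includes differences between runs, and no test was made within a run. Untreated libraries held 18.1 ± 6.77 promoter-proximal reads per 100 gene-body reads (SD, n = 5), and 2 h libraries held 17.3 ± 4.23 (n = 3; two-sided exact permutation p = 0.893). The values were 15.6 ± 2.63 at 6 h (n = 4; exact p = 0.508) and 17.8 ± 1.23 at 24 h (n = 2; exact p = 1, where the smallest p that 21 splits allow is 0.0952). Adjusted over the 3 tests, each p was 1. Within run 2 the difference from the untreated mean of 25.2 was -9.71 at 2 h, -7.39 at 6 h and -7.43 at 24 h. There the treated libraries held 12.7 to 18.7 and the untreated ones 24.6 and 25.9. Within run 1 the 2 h library was higher than the untreated ones by 8.49, and within run 3 the 6 h difference was -1.47.

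**Figure D3:**
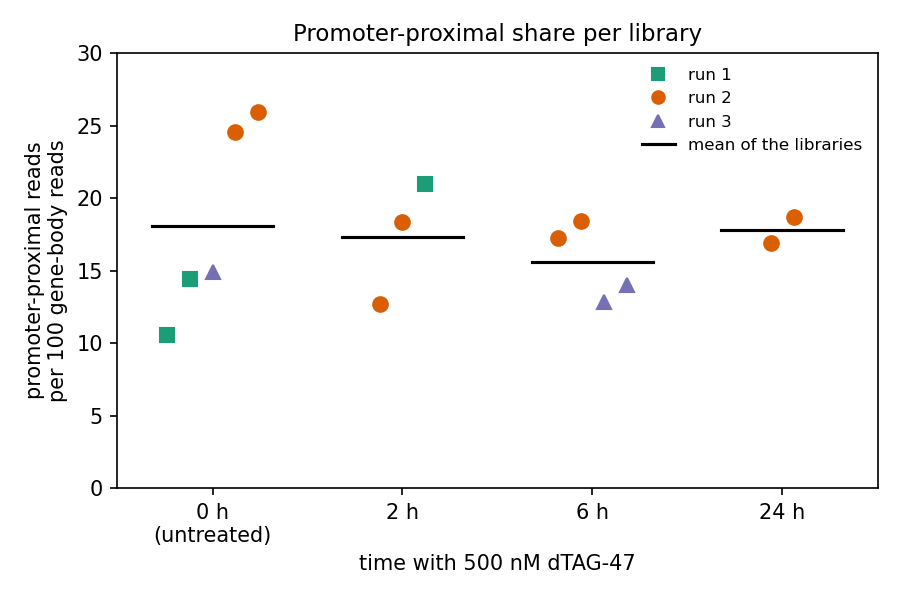
Promoter-proximal reads per 100 gene-body reads in each library by time and run (lines, mean of the libraries). Untreated libraries of run 2 lay highest, with a mean of 25.2, and the 2 h library of run 1, at 20.96, lay above the untreated mean of its run, 12.5.

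Many genes moved in the same direction at all 3 times. Among those called at every time were ABCC5 (0.78 ± 0.071, 1.04 ± 0.066 and 0.9996 ± 0.079 at 2, 6 and 24 h; SE; n = 3, 4 and 2 against 5), TBC1D2 (1.34, 1.71 and 1.38), AAK1, a kinase of clathrin adaptors (0.67, 0.96 and 0.95), and NBR1, an autophagy receptor (0.55, 0.81 and 0.75), which rose. PODXL2, a sialomucin of the CD34 family (-1.33, -1.42 and -1.78), PTPRF, ZNF395 (-1.38, -1.43 and -1.63), EPDR1 (-0.93, -0.95 and -1.31) and PGM1 (-1.06, -1.07 and -1.10) fell. In gene bodies 247 genes rose and 315 fell at all 3 times, of 3416 called at any, against 599 and 631 of 5061 with a run term. Near promoters 1 rose and 1 fell at all 3, against 25 and 35 with a run term. Fold changes correlated across genes, which are not independent replicates, with Spearman coefficients of 0.851 (2 and 6 h), 0.731 (2 and 24 h) and 0.804 (6 and 24 h). The untreated libraries are shared by all 3 comparisons, which alone gave 0.379, 0.302 and 0.325 in 20 simulations. Simulated differences between runs without a time effect gave 0.131, 0.375 and 0.418. When untreated libraries were divided between the comparisons in 10 ways, the coefficients averaged 0.646, 0.524 and 0.618. At 2 and 6 h, 514 genes rose and 609 fell in both, and 1 gene was called in opposite directions. Independent calls would give 91.9 and 107, but the comparisons share untreated libraries. With these divided, and fewer untreated libraries in each comparison, 181 rose and 253 fell in both on average. Near promoters the coefficients were 0.567, 0.681 and 0.546, against 0.382, 0.303 and 0.328 for shared untreated libraries and 0.0572, 0.433 and 0.193 for run differences in the simulations. With untreated libraries divided they averaged 0.250, 0.309 and 0.276, with lowest values of 0.0197, 0.0755 and 3.4e-04.

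A direct test of 24 h against 2 h asked which genes changed between early and late times. DPEP2 (1.68 ± 0.21, SE; adjusted p = 0.00485) and CD33 (0.95 ± 0.12; 0.00538) were higher at 24 h, and TERT (-1.74 ± 0.29; 0.0173) and LOC254896 (-2.09 ± 0.30) were lower. In gene bodies 48 genes passed (edgeR, Benjamini-Hochberg), 41 higher and 7 lower at 24 h, and 420 did with a run term. The count moved to 0 without 24 h A of run 2 and 2 without 24 h B of run 2. It was 5 without 2 h A of run 2 and 11 without 2 h B of run 1. The count was 14 without 2 h B of run 2. Between 6 and 2 h, 0 genes passed in edgeR (813 at an unadjusted p under 0.05), against 163 with a run term and 87 in DESeq2. Near promoters 0 genes passed for 24 h against 2 h (204 unadjusted; 0 in DESeq2) and 0 for 6 h against 2 h (772; 3 in DESeq2). Among the lists, the difference between 24 h and 2 h passed for cholesterol synthesis genes (median -1.46; adjusted p = 1.6e-31, and adjusted p = 0.178 with an estimated correlation) and mitosis genes (0.24; adjusted p = 1.1e-07, and adjusted p = 0.279 with an estimated correlation). Between 6 h and 2 h it passed for ribosome biogenesis genes (-0.22; adjusted p = 2.4e-11, and adjusted p = 0.0217 with an estimated correlation) and cytosolic ribosomal protein genes (-0.16; adjusted p = 1.1e-13, and adjusted p = 0.0217 with an estimated correlation). For cholesterol synthesis genes the value of -1.46 includes a run difference, since run 1 had a 2 h library but none at 24 h. Their median against 0 h at 2 h was 1.75 in run 1 and 0.65 in run 2, and -0.30 at 24 h in run 2. List differences between times were not refitted without single libraries.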

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

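The counts of other splits of the libraries, the tests of run differences, of treatment without SMARCA5 loss and of the length trend, and the test of a common fall in promoter share were chosen only after the result was seen; the splits within runs, the length correction of the cholesterol genes and the test of depth were set before.

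In 14 of 184 groups of 4 or 5 libraries tested, 1 library lay far from the others by Dixon's ratio of its gap to the range, where about 9.2 are given by chance. Values are CPM of that library against the range of the others. In gene bodies of untreated cells these were PFKP (0 h A of run 1, 362 against 405 to 419; ratio 0.755), BNIP3L (0 h A of run 3, 20.99 against 23.1 to 23.7; ratio 0.776) and DNAJB1 (0 h A of run 3, 15.2 against 10.98 to 12.1; ratio 0.743). ESCO2 (0 h B of run 1, 23.2 against 30.4 to 31.7; ratio 0.846) and MPO (0 h A of run 1, 776 against 1016 to 1047; ratio 0.888) also stood apart in single untreated libraries. At 6 h the gene bodies were those of SLC2A1 (6 h A of run 3, 73.9 against 62.2 to 63.5; ratio 0.889) and ENO1 (6 h A of run 3, 252 against 216 to 222; ratio 0.834). Near promoters of untreated cells they were TTC8 (0 h A of run 3, 16.1 against 9.09 to 10.9; ratio 0.739) and OBFC2B (0 h A of run 3, 91.5 against 37.5 to 42.0; ratio 0.917). PIAS3 (0 h A of run 1, 5.52 against 17.5 to 22.1; ratio 0.727), ZNF35 (0 h B of run 1, 254 against 18.9 to 83.4; ratio 0.725) and SPRY1 (0 h A of run 1, 500.4 against 97.48 to 147; ratio 0.877) did so in libraries of run 1. At 6 h promoter-proximal counts of ZNF35 (6 h B of run 2, 17.0 against 9.49 to 10.8; ratio 0.830) and CEBPB (6 h A of run 2, 34.0 against 16.7 to 19.1; ratio 0.862) stood apart.

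Gene-body changes differed between 24 h and 2 h, in edgeR tests of the difference itself (log2, ± SE, n = 2 and 3), for 8 of the genes named in the text. DPEP2, CD33 and PRAM1, a myeloid adaptor, were higher at 24 h than at 2 h: DPEP2 (1.68 ± 0.21, adjusted p = 0.00485), CD33 (0.95 ± 0.12, adjusted p = 0.00538) and PRAM1 (1.24 ± 0.24, adjusted p = 0.0382). So were SLC45A3 (1.34 ± 0.19, adjusted p = 0.00822), C19orf38 (1.01 ± 0.15, adjusted p = 0.00822) and the pro-apoptotic gene BMF (0.79 ± 0.16, adjusted p = 0.0467). Lower at 24 h were TERT (-1.74 ± 0.29, adjusted p = 0.0173) and LOC254896 (-2.09 ± 0.30, adjusted p = 0.00822). These calls rest on both 24 h libraries, since 0 genes pass without 24 h A of run 2 and 2 without 24 h B.

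Of the gene lists, median differences from 2 h to 24 h passed camera in gene bodies for cholesterol synthesis genes (-1.46; adjusted p = 1.6e-31, and adjusted p = 0.178 with an estimated correlation) and mitosis genes (0.24; adjusted p = 1.1e-07, and adjusted p = 0.279 with an estimated correlation). They passed for haematopoietic and leukaemia transcription factors (0.26; adjusted p = 4.1e-06, and adjusted p = 0.224 with an estimated correlation) and stem and progenitor surface genes (0.43; adjusted p = 1.0e-05, and adjusted p = 0.0217 with an estimated correlation). All 24 h libraries were of run 2, while the 2 h group included run 1. The cholesterol value therefore includes a run difference, as within run 2 the medians against 0 h were 0.65 at 2 h and -0.30 at 24 h. Lists that were lower at 24 h than at 2 h were ribosome biogenesis genes (-0.11; adjusted p = 0.0184, and adjusted p = 0.270 with an estimated correlation), cytosolic ribosomal protein genes (-0.095; adjusted p = 5.5e-04, and adjusted p = 0.242 with an estimated correlation) and heat shock and unfolded protein response genes (-0.25; adjusted p = 0.00159, and adjusted p = 0.242 with an estimated correlation). From 2 h to 6 h they were ribosome biogenesis genes (-0.22; adjusted p = 2.4e-11, and adjusted p = 0.0217 with an estimated correlation), cytosolic ribosomal protein genes (-0.16; adjusted p = 1.1e-13, and adjusted p = 0.0217 with an estimated correlation), heat shock and unfolded protein response genes (-0.18; adjusted p = 5.0e-04, and adjusted p = 0.232 with an estimated correlation) and cholesterol synthesis genes (-0.52; adjusted p = 8.7e-11, and adjusted p = 0.339 with an estimated correlation). Near promoters, 24 h differed from 2 h for mitosis genes (0.27; adjusted p = 3.3e-04, and adjusted p = 0.270 with an estimated correlation) and cholesterol synthesis genes (-0.40; adjusted p = 1.8e-07, and adjusted p = 0.178 with an estimated correlation), and 6 h from 2 h for interferon-stimulated genes (0.30; adjusted p = 0.0224, and adjusted p = 0.242 with an estimated correlation) and cholesterol synthesis genes (-0.12; adjusted p = 5.0e-04, and adjusted p = 0.270 with an estimated correlation).

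Chance was not excluded for the 2 h gene-body count of 1365: 3 of 56 splits of the 0 h and 2 h libraries gave as many, the highest other 2212. That split put 0 h A and B of run 1 with 0 h B of run 2 against the rest, which held all 2 h libraries. The other higher split (1624) also kept the 2 h libraries together. Both therefore retain part of the treatment contrast and do not measure chance alone. With a run term the count was 3979. Chance was also not excluded for the promoter-proximal count of 6 (3 splits, highest other 15). The same holds for 7 gene-body lists (20 splits, highest other 10) and 1 promoter-proximal list (40 splits, highest other 3). For the 2 genes with a shift between promoter and gene body, 2 splits gave as many (highest other 27), a share under 0.05. These splits ignore the runs, so they do not exclude chance for a count of 2. That count fell to 0 without any of 7 libraries, and 6 of 70 calls in simulated data were false. At 6 h, over 100 splits drawn from 126, few gave as many as the 3010 gene-body calls (2 splits; highest other 3448), a share under 0.05. These splits also ignore the runs, and those within runs, given last, cannot tell, so chance is not settled by them. The highest split set all untreated libraries of runs 1 and 2 against the rest, which held all 6 h libraries. Chance was not excluded for 163 promoter-proximal calls (9; 1379), 31 shifts between regions (7; 943, from a split of run 2 against the rest, with 39 calls under a run term), 6 gene-body lists (44; 10) and 2 promoter-proximal lists (25; 4). Counts several times the real ones point to a structure of the libraries. Lists are counted here with adjustment over the 23 lists of 1 region and comparison, not over all tests as in the report, so these counts differ. Between 6 h and 2 h, with 35 splits, the splits cannot tell for 0 gene-body calls (35; 20) or 0 promoter-proximal calls (35; 1), since every split gives at least 0. Chance was not excluded for 6 gene-body lists (9; 9) or 3 promoter-proximal lists (4; 4). For splits within runs under a run term, 18 for each comparison, the share cannot go under 0.05. There 1 split, the real one, gave as many calls in each: 3979 in gene bodies at 2 h (highest other 11), 460 near promoters (100), 2762 in gene bodies at 6 h (57) and 224 near promoters (7).

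The rise of cholesterol synthesis genes at 2 h (median log2 1.13) was present within both runs, at 1.75 in run 1 and 0.65 in run 2. Untreated libraries lay at -0.22 to -0.49 and 2 h libraries at 0.37 to 1.32 (median deviation of the list). These values argue against a run difference as the whole cause of the rise, though run 1 held a single 2 h library. The bound of 0.10 for run 2 came from random lists of genes drawn independently. It does not measure how far a list of genes that move together varies between libraries. After removal of the trend with gene length the median was 1.16, which argues against length. At 6 h the median was -0.042 in run 2 and 0.83 in run 3, so a run difference could account for that rise. The tables hold 0 treated libraries without the degron, so an effect of the compound or of handling cannot be told apart from loss of SMARCA5. Loss of SMARCA5 stays open as the biological explanation.

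Shorter genes were higher and longer genes lower at 2 h, with a Spearman coefficient of -0.347 between gene length and log2 change across genes, which are not independent replicates. It was present in both runs, at -0.304 and -0.378, which argues against a difference between runs. Pairs of single untreated libraries, most of them from different runs, differed by a trend of up to 0.364 in absolute value. That largest value does not show how far untreated libraries of the same run differ. Variation between libraries without treatment therefore stays open as an explanation of the trend at 2 h. The coefficients were -0.276 at 6 h and -0.205 at 24 h. An effect of SMARCA5 loss on long genes was not tested apart from this.

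The promoter-proximal share was lower in treated than in untreated libraries of run 2. In run 1 the 2 h difference was 8.49 reads per 100, and in run 3 the 6 h difference was -1.47. Too few libraries per run keep a fall common to all runs open, and it cannot be told apart from a run effect. Depth is argued against, since untreated totals in run 2 (11199143 to 16138846 reads) overlap treated ones (11182894 to 14133770). Over 14 libraries the share and the gene-body total had a Spearman rho of -0.314 (permutation p = 0.273) and a Pearson r of -0.369 (permutation p = 0.193; -0.503 without the 2 libraries farthest from the median total).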

How the results depend on the processing

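The alternatives with a run term, run 2 alone, without both untreated libraries of run 1, with gene-body size factors, DESeq2 with a run term, and leaving out libraries for lists, times and the difference between regions were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers, but a run term blocks libraries by run. The term for the first against the later deposited samples was fitted as run 2 against the others, the only run with 2 libraries at each time, as the first deposit has. It gave 1864, 3528 and 1121 calls in gene bodies and 41, 595 and 25 near promoters. Pseudocounts, another adjustment of the authors' p-values and correlated errors between regions were set for the case without raw counts and did not apply. Centring fold changes on the median moves no correlation between times. Calls in gene bodies (main 1365, 3010 and 1111 at 2, 6 and 24 h), near promoters (6, 163 and 20), for the difference between regions (2, 31 and 6), for 24 h minus 2 h in gene bodies (48) and for lists (18) stayed within 1.5 times with 1 transcript per symbol, DESeq2 size factors and no filter, where run, and the difference between regions did with centring on the median gene. With an adjusted p under 0.01 the counts were 404, 1243 and 395 in gene bodies, 1, 32 and 3 near promoters, 0, 0 and 0 for the difference between regions (limma) and 8 for 24 h minus 2 h. A 1.5-fold minimum gave 470, 909 and 578 in gene bodies, where 66.9% of the 6 h calls rose against 50.9%. A mean count of at least 100 gave 2, 69 and 7 near promoters and 10 and 2 for the difference between regions at 6 and 24 h. These fewer calls follow from the stricter limits or the smaller set of genes; for the settings below the cause was not tested. DESeq2 gave 74, 537 and 104 near promoters, 156 for 24 h minus 2 h, 87 for 6 h minus 2 h (main 0) and 3 for the latter near promoters (main 0). DESeq2 with a run term gave 4125 and 2304 in gene bodies at 2 and 24 h, and 2930 at 6 h, the counts and medians of the deposited gene-body tables, with 704, 358 and 242 near promoters, 671 and 409 between times in gene bodies, and 2 and 2 near promoters (main 0 and 0). With a run term edgeR gave 3979 and 2045 in gene bodies at 2 and 24 h, 460 and 141 near promoters, 420 and 163 between times, and 115 and 25 for the difference between regions. Run 2 alone gave 3938 and 4447 in gene bodies at 2 and 24 h, 1682, 938 and 1430 near promoters, 2309 and 1707 between times, 4 for 24 h minus 2 h near promoters, and 741, 215 and 655 for the difference between regions. Fits of only the groups compared, with fewer libraries to estimate the spread, gave 547, 1795 and 351 in gene bodies and 3, 39 and 8 near promoters. Without both untreated libraries of run 1 there were 0, 48 and 6 near promoters, 207 and 97 between times, and 0 and 0 for the difference between regions at 2 and 6 h. Gene-body size factors gave 1, 29 and 4 near promoters, with 20.7% of the 6 h calls rising against 41.7%. List calls fell to 4 at a correlation of 0.05, to 0 with an estimated one and to 0 with that and a run term. Leaving out 1 library gave 322 to 2248, 1854 to 3770 and 161 to 1487 in gene bodies, 0 to 50, 33 to 817 and 0 to 36 near promoters, 0 to 3, 0 to 142 and 0 to 11 for the difference between regions, 11 to 21 list calls, 0 to 14 for 24 h minus 2 h, and 0 to 0, 0 to 0 and 0 to 0 for the other contrasts between times; a lone 24 h library was assumed to vary like the other groups. Reversed values were those of cholesterol synthesis genes in gene bodies at 6 h in run 2 alone (-0.046), SMARCA5 in gene bodies at 6 h in run 2 alone (0.039) and SMARCA5 near the promoter at 24 h with DESeq2 and a run term (-0.017), edgeR with one (-0.015) or the term for deposit (-0.060). The median of haematopoietic factors at 2 h was 0.010 without 2 h A of run 2 (main -0.043), though camera still pointed down. A set of 192 gene-by-time results, 186 of them called, was taken from the genes named in the text or by the rule. It does not hold all of them, so calls lost with a run term that are named above can lie outside it. Of its 3963 alternative values, 3496 kept their direction and side of the threshold, 463 were no longer past it and 4 reversed, as above. In this set calls were lost in 244 of 1528 fits without 1 library and for 61 values at the 0.01 threshold. Losses numbered 41 with only the groups compared, 38 without both untreated libraries of run 1 and 36 with the fold minimum. There were 21 of 31 with gene-body size factors, 9 with the term for deposit and 3 with a run term. Of the list calls in gene bodies, cholesterol genes at 6 h (0.434), heat shock genes at 2 h (0.106) and remodellers at 2 h (0.165) were lost in run 2 alone. Lost without both untreated libraries of run 1 were cholesterol genes at 6 h (0.0859), ribosomal protein genes at 6 h (0.0502) and remodellers at 2 h (0.227). The rank-based test lost interferon genes at 24 h (0.0514), glycolysis genes at 2 h (0.0514), glycolysis genes at 6 h (0.188), glycolysis genes at 24 h (0.188) and haematopoietic factors at 2 h (0.198). Others lost were interferon genes at 24 h (0.101) with a mean count of at least 100 and replication genes at 2 h (0.0696) with a run term, which gained 6 list calls. Near promoters these were cholesterol genes at 2 h (0.0616), mitosis genes at 24 h (0.539), interferon genes at 6 h (0.0568) and ZNF genes at 6 h (0.483) in run 2 alone, and mitosis genes at 24 h (0.111) and ZNF genes at 6 h (0.221) without the untreated libraries of run 1. They were interferon genes at 6 h (0.0509) and ZNF genes at 6 h (0.0611) in the rank-based test, interferon genes at 6 h (0.258) with the minimum count and mitosis genes at 24 h (0.246) and ZNF genes at 6 h (0.122) with a run term. What depth limits was not tested by varying it. At these depths 2-fold changes near promoters were recovered for 32.8, 19.4 and 16.4% of simulated genes. Run 2 alone, with lower totals, gave more calls. Near promoters its libraries of the same time correlated with Spearman coefficients of 0.968 to 0.986, against 0.862 to 0.971 between runs. The higher count in run 2 therefore gives no measure of the effect of depth.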

Other observations

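The genes that differed between 24 h and 2 h were described after their values were seen. The lists below and their tests were fixed before the data were examined, while the choice of what to describe here came after. No further hypothesis was tested in this part.

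Regulators of apoptosis moved in both directions and the list as a whole did not pass at any time (median log2 change 0.027, 0.0072 and -0.0047 at 2, 6 and 24 h; adjusted p = 0.921, 0.858 and 0.676; 19 measured). At 6 h 5 rose and 3 fell (adjusted over the list alone, 6 and 3). BCL2L1, which encodes the survival factor BCL-XL, rose at 2 h (0.36 ± 0.090, SE, n = 3 against 5) and 6 h (0.36 ± 0.083, n = 4), and CFLAR, which restrains death receptor signalling, fell (-0.46 ± 0.089 and -0.46 ± 0.082). At 24 h (n = 2) the pro-apoptotic gene BMF (0.83 ± 0.14), APAF1, the core of the apoptosome (0.50 ± 0.13), and BCL2L1 (0.40 ± 0.10) rose. BCL2L1 lost its 2 h call without 2 h B of run 1 (0.133), and at 24 h the calls were lost without 24 h B of run 2 (0.0597) for BMF, 24 h A of run 2 (0.135) or 24 h B of run 2 (0.203) for APAF1 and 24 h A of run 2 (0.228) or 24 h B of run 2 (0.149) for BCL2L1. Cohesin and CTCF genes did not move together (median -0.14; adjusted p = 0.426 at 6 h, 17 measured). ESCO2, a cohesin acetyltransferase, rose at 6 h (0.61 ± 0.12) and 24 h (0.64 ± 0.14), while the cohesin subunit STAG1 fell (-0.45 ± 0.094 and -0.57 ± 0.12), as did PDS5A at 6 h (-0.38 ± 0.078). The 24 h calls were lost without 24 h A of run 2 (0.152) or 24 h B of run 2 (0.0977) for ESCO2 and 24 h A of run 2 (0.109) or 24 h B of run 2 (0.110) for STAG1.

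Besides DPEP2 and CD33, PRAM1, a myeloid adaptor (1.49 ± 0.21 against 0 h, SE, n = 2 against 5), SLC45A3 (1.03 ± 0.17) and C19orf38 (1.15 ± 0.13) rose at 24 h and kept that call without either 24 h library. Among 7 stem and progenitor surface genes KIT, the stem cell factor receptor, fell at 2 h (-0.48 ± 0.12) and 6 h (-0.38 ± 0.11), and the integrin ITGA4 fell at 2 h (-0.61 ± 0.18). KIT lost its calls without 2 h A of run 2 (0.0551), 2 h B of run 2 (0.0760) or 2 h B of run 1 (0.0973) at 2 h and 6 h A of run 3 (0.0680) or 6 h B of run 3 (0.0714) at 6 h, and ITGA4 without 0 h A of run 1 (0.0729), 0 h B of run 1 (0.0776), 0 h B of run 2 (0.0527), 2 h A of run 2 (0.0693), 2 h B of run 2 (0.0876) or 2 h B of run 1 (0.198). The list's difference between 24 h and 2 h (median 0.43; adjusted p = 1.0e-05) held with an estimated correlation (adjusted p = 0.0217). That difference rests on 7 genes and on 24 h libraries of run 2 alone, and it was not refitted without single libraries. CEBPE, a transcription factor of granulocytes (1.19 ± 0.33), HHEX, a homeobox factor (0.77 ± 0.20), DUSP6, an ERK phosphatase (0.62 ± 0.13), and MPO, which encodes myeloperoxidase (0.38 ± 0.11), rose at 24 h. Without 24 h A or B of run 2 these 4 calls were lost (adjusted p from 0.102 to 0.291), and those of CEBPE (0.0619), HHEX (0.0507) and MPO (0.0578) also without 0 h B of run 1. The granulocyte and monocyte list did not pass at 24 h (median 0.40; adjusted p = 0.217; 8 measured).

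Other lists did not pass in gene bodies at any time. Among p53 targets (16 measured; medians 0.19, 0.20 and 0.10 at 2, 6 and 24 h; lowest adjusted p = 0.422), FDXR, a ferredoxin reductase, rose at 6 h (0.94 ± 0.24). Among immediate early genes (22; -0.044, 0.040 and 0.22; 0.139), NR4A2, an orphan nuclear receptor, rose at 6 h (0.93 ± 0.22). The medians were -0.062, -0.089 and 0.096 for NF-kB and inflammatory genes (17; lowest adjusted p = 0.676), 0.12, 0.062 and -0.027 for oxidative phosphorylation (36; 0.371), -0.018, 0.010 and -0.0068 for pausing and elongation factors (29; 0.872), 0.0025, -0.073 and -0.063 for RNA polymerase II and general factors (39; 0.497), -0.024, -0.080 and -0.067 for ZNF genes (372; 0.201) and -0.19, -0.015 and -0.25 for HOX genes (7; 0.855). EPCAM, an epithelial adhesion gene, fell at all 3 times (-0.73 ± 0.11, -0.59 ± 0.098 and -0.69 ± 0.13), and its 24 h call was lost without 24 h A of run 2 (0.0934).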
